A study of Solanum lycopersicum with 9 samples.

How the data were processed

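Leaf mRNA of tomato (Solanum lycopersicum, the dwarf cultivar Micro-Tom) was profiled by Illumina RNA sequencing in 3 groups of 3 libraries: wild type (WT), a CRISPR mutant of the transcription factor gene SlWRKY37 (CR) and a line described as overexpressing it (OE). Per the labels, the fourth leaf of plants 21 days (3 weeks) old was taken, libraries were built from 1 µg of total RNA, and each group held 3 biological replicates. Groups and replicate numbers came from the sample titles. Because SlWRKY37 was not higher in the OE group than in WT, the libraries of that group are called the libraries labelled OE throughout.

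The authors deposited 3 tables, 1 for each pair of groups, with 40229 genes each, and a library had the same values in every table (0 cells differed). Per the file headers, each table held estimated counts per gene and library, and 14.9% to 15.9% of the cells of a library were not whole numbers. The deposited TPM values (transcript abundance scaled for length and depth) summed to between 921881 and 989700 per library, and the authors' group columns were means of these. The deposited fold changes and log2 fold changes, p-values and adjusted p-values came from the authors' own DESeq2 comparisons, per the file headers and names, and ran as CR over WT, OE over WT and OE over CR. In those tables the genes marked significant all had an adjusted p of at most 0.05 and an absolute log2 fold change of at least 1. The aligner, the counting program, its use of strand, the genome build and any read filter are not given in the sources used here. Genes were named by the identifiers and descriptions in the deposited tables. Neighbouring genes were those within 10 places in the order of the identifier numbers, among tested genes on the same chromosome. Genome coordinates were not analysed here. Genes that overlap, lie antisense to another gene or have near-identical copies (phenylalanine ammonia-lyases, histones, glucanases, proteases and chlorophyll a-b binding proteins among those named) have uncertain counts, since the counting could divide their reads.

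The estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM scaling, filterByExpr by group) in R 4.3.3. All 9 libraries entered 1 fit with the group as its term, which left 21161 genes, and p-values were adjusted by Benjamini-Hochberg. A gene was called at an adjusted p under 0.05, and a second count required a fold of at least 2. Every adjusted p of a gene given for this work comes from that test unless another tool is named. Levels are TMM-scaled CPM (counts scaled to library size), as mean ± SD over the 3 libraries of a group, and log2 fold changes carry a standard error (SE). Library totals were 20770591, 20279208 and 17039827 for WT, 18800810, 19797322 and 19499201 for CR, and 19223109, 21208641 and 18525765 for the libraries labelled OE. A gene without counts in a group was given a floor of 3 counts over the group, which is 0.052 CPM in WT, 0.052 in CR and 0.051 in the libraries labelled OE and covers counting error only. The 95% intervals come from the fit and take in the spread between libraries. The procedure was tested on simulated counts with known changes in 195 or 196 tested genes per comparison. For CR against WT it recovered 10.8%, 58.5% and 84.6% of genes changed 1.5, 2 and 4 times, with 7.4% false calls (20903 genes). For OE against WT the shares were 6.2%, 55.4% and 78.8%, with 4.2% false calls (20890 genes). For CR against OE they were 12.3%, 60% and 80%, with 3.9% false calls (20898 genes).

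The design, the alternatives, 30 gene lists and the rule for named genes were chosen before the data were examined. The lists were matched on the description text and covered abscisic acid, autophagy, auxin, carbon fixation, cell cycle and histones, cell wall loosening, chlorophyll breakdown, chlorophyll synthesis, the circadian clock, cytokinin, cytosolic ribosomal proteins, epidermis and cuticle, ethylene, gibberellin, glandular trichomes, heat shock proteins, jasmonate signalling, jasmonate synthesis, NAC factors, nitrogen remobilisation, organelle-encoded transcripts, pathogenesis-related proteins, phenylpropanoids and flavonoids, photosystems and light harvesting, phytochrome and light signalling, reference genes, senescence markers, vascular markers, wound and jasmonate defence, and WRKY factors. The organelle list found no gene (1 list without members). The other 29 were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists and again with the correlation estimated per list. No list call at the preset correlation held with an estimated correlation. In CR vs WT the estimate was -0.001 for senescence markers and -0.012 for the clock, both below the preset 0.01. Correlated members thus do not account for the loss of those calls. Enrichment of KEGG pathways and GO biological processes used a one-sided hypergeometric test on terms of 10 to 500 genes. The background was the tested genes with a term, 4951 for KEGG (114 terms) and 9420 for GO (271 terms).

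The named genes were SlWRKY37, SlSGR1 and SlWRKY53 in each comparison, whether called or not. To these were added the 5 called genes with the largest rise and the 5 with the largest fall among described genes whose libraries did not overlap between groups, with at least 1 CPM in 1 of the groups. From each list came up to 2 called members per direction with the smallest adjusted p, and genes whose number the list itself stated. Among these, the genes printed were mostly chosen, after their values were seen, from those called under every alternative. Over all 254 calls of named genes, 621 of 4302 calls under an alternative were lost. One of the genes changed in opposite directions is not reported here. Alternatives were RLE scaling, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, only the groups compared, a term for the replicate number, each library left out in turn, and, for lists, an estimated correlation and fry. For both lines against WT a fit with only the groups compared does not exist. An alternative planned for files with normalized values alone did not apply, since counts were deposited. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3.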

Results

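Transcript levels were measured in the fourth leaf of wild-type tomato, of a CRISPR mutant of SlWRKY37 (CR) and of plants labelled as overexpressing SlWRKY37 (OE), with 3 biological replicates in each group. SlWRKY37 belongs to the WRKY family of plant transcription factors, and the series concerns leaf senescence induced by jasmonate and darkness, which by its title was eased in the knock-out. The leaves sequenced here carry no label of either treatment. Total estimated counts ran from 17039827 to 21208641 per library, and 11039 of 40229 genes had 0 counts in every library. Over log2 CPM, the first principal component (34.4% of the variance) placed WT between -70 and -24.9, the libraries labelled OE between -6.7 and 15.1, and CR between 44.1 and 54.9. The second component (19.3%) set the libraries labelled OE apart. WT replicate 3 lay at 66.2 on the third component (16.2%). OE replicate 1 at 29 and CR replicate 1 at 20 came next, and every other library was negative. The Pearson correlation across genes of WT replicate 1 was 0.984 with WT replicate 2 and 0.954 with WT replicate 3. WT replicate 3 correlated at 0.958 with WT replicate 2. With the libraries of CR and those labelled OE it ran from 0.94 (CR replicate 3) to 0.956 (OE replicate 1). WT replicate 3 was thus about as close to OE replicate 1 as to the other WT libraries.

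The targeted gene was examined first, taken as the gene whose deposited description is WRKY transcription factor 37. Whether that gene is the one edited and overexpressed was not tested. SlWRKY37 (Solyc01g079360.4) had 36.8 ± 3.47 CPM in WT, 24.2 ± 5.81 in CR and 36.8 ± 7.81 in the libraries labelled OE (SD, n = 3 each). In CR its log2 fold change against WT was -0.61 (SE 0.19, 95% interval -1.04 to -0.17), which missed the threshold at an adjusted p of 0.0634. The 3 CR libraries (30.6, 19.2 and 22.8 CPM) all lay below the 3 WT libraries (33.1, 37.4 and 40 CPM), with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. The difference was called by DESeq2 (-0.59, adjusted p = 0.0318) and without CR replicate 1 (-0.81, adjusted p = 0.0285), and the adjusted p ran from 0.0285 to 0.2 over the alternatives. In the libraries labelled OE (29.8, 45.2 and 35.2 CPM) the log2 fold change against WT was 0.00 (SE 0.19, adjusted p = 0.998, exact permutation p = 1), and its 95% interval allowed a rise of at most 1.35-fold. CR against the libraries labelled OE gave -0.60 (adjusted p = 0.134, exact permutation p = 0.2). The authors' deposited table lists -0.59 for CR over WT (adjusted p = 0.0275), 0.01 for OE over WT (adjusted p = 0.99) and 0.60 for OE over CR (adjusted p = 0.0792). The transcript level alone does not show whether the mutant makes a working protein, and the edited site was not analysed here.

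SlWRKY53 (Solyc08g008280.3), another WRKY factor, was 5.78-fold lower in CR (32.6 ± 11.7 CPM) than in WT (188 ± 29.3 CPM), a log2 fold change of -2.53 (SE 0.24, adjusted p = 0.000306). Its level in the libraries labelled OE was 188 ± 22.4 CPM, with a log2 fold change against WT of 0.00 (adjusted p = 1). SlSGR1 (Solyc08g080090.3, green flesh), which starts chlorophyll breakdown by removing its magnesium, had 66.7 ± 19.9 CPM in WT, 48.4 ± 7.34 in CR and 50.1 ± 14.8 in the libraries labelled OE. It was not called in CR (-0.46, adjusted p = 0.237) or in the libraries labelled OE (-0.41, adjusted p = 0.367).

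**Figure D1:**
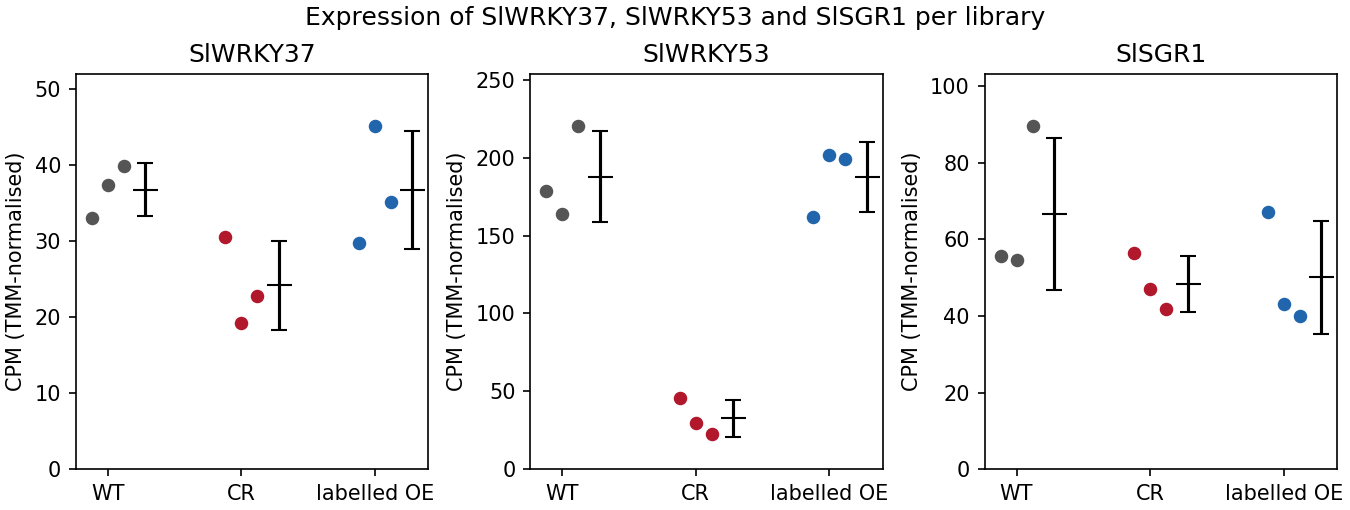
TMM-normalised CPM (linear axis from 0) of SlWRKY37, SlWRKY53 and SlSGR1 in each library of WT, CR and the group labelled OE, with a bar for the mean and SD over 3 libraries. SlWRKY53 was at 32.6 CPM in CR against 188 CPM in WT, while SlWRKY37 averaged 36.8 CPM both in WT and in the libraries labelled OE.

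To ask what the mutation of SlWRKY37 changes in the leaf, CR was compared with WT. Single genes of defence, hormone synthesis and senescence were among those lower in the mutant, while the jasmonate synthesis list (4 of 32 lower, 1 higher, camera adjusted p = 0.212) and the ethylene list (14 of 132 lower, 15 higher, camera adjusted p = 0.257) were not called by camera (fry adjusted p = 0.0369 and 0.373). Lipoxygenase D (Solyc03g122340.3), which starts jasmonate synthesis from linolenic acid, was 3.1-fold lower (40.4 ± 3.81 against 125 ± 15.2 CPM, adjusted p = 0.000236). The cysteine protease PIP1 (Solyc02g077040.4) was 5.13-fold lower (181 ± 37.7 against 926 ± 197 CPM, adjusted p = 0.000227). ACC oxidase 1 (Solyc07g049530.3), which makes ethylene from its precursor, was 5.03-fold lower (371 ± 110 against 1860 ± 462 CPM, adjusted p = 0.00249). An ACC synthase (Solyc08g081550.4), which makes that precursor, was 2.43-fold lower (adjusted p = 0.0016). A phenylalanine ammonia-lyase (Solyc09g007910.4), the entry enzyme of phenylpropanoid synthesis, was 5.21-fold lower (55.8 ± 8.91 against 291 ± 54.5 CPM, adjusted p = 0.000642). In all, 3268 of 21161 genes were called, 1167 higher and 2101 lower, and 1282 of them changed at least 2-fold (275 higher, 1007 lower). The authors' deposited table marks 1467 genes for this comparison (336 higher, 1131 lower), of which 1228 were also called here. The number called was 1528 without WT replicate 1, 1664 without WT replicate 2, 5101 without WT replicate 3 (2237 higher, 2864 lower), 1770 without CR replicate 2 and 1454 without CR replicate 3.

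Among the WRKY factors, 2 of 62 tested members rose, 23 fell and 37 were not called in CR (7 and 30 adjusted over the list alone). WRKY51 (Solyc04g051690.4) fell 3.51-fold and WRKY81 (Solyc09g015770.3) from 526 ± 41.6 to 176 ± 22.6 CPM, each at an adjusted p of 0.000227. WRKY3 (Solyc02g088340.4, 2.01-fold) and WRKY28 (Solyc12g011200.3, 3.07-fold) rose. The list was lower as a whole (median log2 fold change -0.53, camera adjusted p = 1.38e-09; adjusted p = 0.108 with an estimated correlation). Of 18 senescence markers, 0 rose and 8 fell (0 and 9 adjusted over the list alone), including PIP1 and the senescence-associated gene 21 (Solyc12g099465.1, 3.71-fold, adjusted p = 0.00068). PIP1, which the text match brought in, is described as a phytophthora-inhibited protease. Of the members entered by number, Solyc02g088180.3 fell 1.65-fold (adjusted p = 0.0193) and Solyc05g052980.4 1.39-fold (0.0242). Solyc06g069710.3 (log2 fold change -0.26, adjusted p = 0.749) and Solyc03g115850.3 (0.19, adjusted p = 0.459) were not called. The median of that list was -0.51 (camera adjusted p = 3.15e-05; adjusted p = 0.0687 with an estimated correlation), and 5 members fell without WT replicate 2 or without CR replicate 3.

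Among the cytosolic ribosomal proteins, structural parts of the translation machinery, 139 of 287 tested members fell, 2 rose and 146 were not called (191 and 8 adjusted over the list alone). The falls were shallow: 60S L18a (Solyc02g070650.2) fell 1.8-fold and 60S L22 (Solyc01g099830.3) 1.73-fold, and the list median was -0.44 (camera adjusted p = 2.01e-16; adjusted p = 0.561 with an estimated correlation). The list's median deviation from the mean of all libraries was 0.29, 0.27 and 0.17 in WT, -0.02, -0.35 and -0.19 in CR, and 0.00, 0.02 and -0.20 in the libraries labelled OE. The count of members that fell was 30 without WT replicate 1, 35 without WT replicate 2, 47 without CR replicate 2 and 28 without CR replicate 3.

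Of 94 tested pathogenesis-related genes, 22 fell and 3 rose in CR (25 and 3 adjusted over the list alone; median -0.26, camera adjusted p = 0.00104; adjusted p = 0.561 with an estimated correlation). Pru ar 1 (Solyc12g096960.2), a gene of the class 10 allergen family, fell 9.45-fold and a thaumatin-like gene (Solyc12g056390.1) 9.19-fold. In the phenylpropanoid and flavonoid list 19 of 79 members fell and 7 rose (25 and 7 adjusted over the list alone; median -0.27, camera adjusted p = 0.0378; adjusted p = 0.5 with an estimated correlation). That call was lost without CR replicate 1 (adjusted p = 0.0713), CR replicate 3 (0.0531) or OE replicate 3 (0.0536). The members that fell in it numbered 8 without WT replicate 1, 10 without WT replicate 2 and 8 without CR replicate 3.

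The lists called higher in CR were light signalling, the clock, carbon fixation and the photosystems, and none of these calls held with an estimated correlation. Of 50 phytochrome and light signalling genes 12 rose and 0 fell (15 and 1 adjusted over the list alone; median 0.24, camera adjusted p = 3.87e-05; adjusted p = 0.314 with an estimated correlation). They were led by a PHYTOCHROME KINASE SUBSTRATE 3-like gene (Solyc06g069880.1, 3.2-fold, adjusted p = 0.000572). The count that rose was 6 without WT replicate 2, 7 without CR replicate 2 and 6 without CR replicate 3. GIGANTEA (Solyc12g056650.2), a clock component that peaks late in the day, rose 1.46-fold (593 ± 18.8 against 405 ± 9 CPM, adjusted p = 0.00338). A second GIGANTEA gene (Solyc04g071990.3) had a log2 fold change of 0.07 (adjusted p = 0.685), and LATE ELONGATED HYPOCOTYL (Solyc10g005080.3) one of -0.04 (adjusted p = 0.957), with the sign reversed without WT replicate 3 (0.28), CR replicate 1 (0.04) or CR replicate 2 (0.11). The response regulator APRR5 (Solyc06g069690.4) fell 1.43-fold (adjusted p = 0.0129), a call lost without WT replicate 1 (adjusted p = 0.0647), WT replicate 2 (0.0604) or CR replicate 3 (0.0663). The clock list as a whole had 4 members higher and 1 lower of 29 (4 and 1 adjusted over the list alone; median 0.19, camera adjusted p = 0.0309; adjusted p = 0.24 with an estimated correlation). The clock call was lost without WT replicate 1 (adjusted p = 0.0562). Carbon fixation genes had 2 of 24 members higher and 0 lower (0 and 0 adjusted over the list alone; median 0.35, camera adjusted p = 0.00812; adjusted p = 0.72 with an estimated correlation). It was lost without WT replicate 1 (adjusted p = 0.116) and with fry (0.239). The photosystem and light harvesting list had 4 of 102 members higher and 1 lower (0 and 1 adjusted over the list alone; median 0.21, camera adjusted p = 0.0218; adjusted p = 0.75 with an estimated correlation). It was lost without WT replicate 1 (adjusted p = 0.25), CR replicate 1 (0.119) or CR replicate 2 (0.0667), and with fry (0.36). The photosystem list's median deviation was -0.48, -0.15 and 0.02 in WT and 0.16, 0.01 and -0.15 in CR. CR replicates 2 and 3 thus lay below WT replicate 3.

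The hormone lists were not called by camera in CR, while fry called gibberellin (adjusted p = 0.0119) and jasmonate synthesis (0.0369). Of 32 jasmonate synthesis genes 4 fell and 1 rose (4 and 2 adjusted over the list alone; camera adjusted p = 0.212). Besides lipoxygenase D, allene oxide synthase (Solyc04g079730.1, CR vs WT log2 fold change -1.51, SE 0.37, adjusted p = 0.0245) was lower, a call lost without WT replicate 1 (adjusted p = 0.0675), WT replicate 2 (0.067), CR replicate 2 (0.0781) or CR replicate 3 (0.105). Allene oxide cyclase (Solyc02g085730.3), the next enzyme, had a log2 fold change of -0.58 (adjusted p = 0.211), and OPR3 (Solyc07g007870.3) one of -0.39 (adjusted p = 0.0707). The cyclase was called without OE replicate 2 (adjusted p = 0.0389) and with only CR and WT fitted (0.0329). OPR3 was called without WT replicate 3 (0.0302) or OE replicate 2 (0.0416), with only CR and WT fitted (0.046) and by DESeq2 (0.0378). Jasmonate signalling had 1 of 11 members higher, the Tify domain gene Solyc06g065650.3 (1.56-fold, adjusted p = 0.00297), and 1 lower (1 and 2 adjusted over the list alone; camera adjusted p = 0.811). Ethylene genes went both ways, with 15 of 132 higher and 14 lower (18 and 20 adjusted over the list alone; camera adjusted p = 0.257), and ethylene response factor 4 (Solyc05g052030.1) rose 2.66-fold. The counts for abscisic acid were 6 of 62 higher and 7 lower (6 and 7 adjusted over the list alone; camera adjusted p = 0.866). The abscisic acid receptor PYL1 (Solyc08g076960.1, 2.69-fold) and an ABA 8'-hydroxylase (Solyc04g078900.3, 2.71-fold), which breaks the hormone down, rose. The gene notabilis (Solyc07g056570.1), the 9-cis-epoxycarotenoid dioxygenase of its synthesis, fell 1.96-fold. Cytokinin genes had 4 of 41 higher and 4 lower (7 and 4 adjusted over the list alone; camera adjusted p = 0.212), among them the type-A response regulator ARR9 (Solyc10g079700.2, 4.47-fold higher). Of 24 gibberellin genes 0 rose and 5 fell (0 and 5 adjusted over the list alone; camera adjusted p = 0.0592), led by gibberellin 2-oxidase 3 (Solyc01g079200.4, 9.38-fold lower), which inactivates the hormone. Auxin genes had 10 of 111 higher and 4 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.0562), with IAA4 (Solyc06g053840.3) 1.96-fold higher.

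Chlorophyll breakdown had 2 of 15 members higher and 1 lower in CR (3 and 1 adjusted over the list alone; camera adjusted p = 0.0592). Pheophytinase (Solyc01g088090.3), which removes the phytol tail, rose from 64.4 ± 8.79 to 100 ± 8.22 CPM (adjusted p = 0.00647), and chlorophyllase 2 (Solyc12g005300.2) fell 2.01-fold. The other member that rose was a chlorophyllase (Solyc09g065620.3, 2.91-fold, adjusted p = 0.0306). In chlorophyll synthesis (1 of 31 higher and 1 lower, also 1 and 1 adjusted over the list alone; camera adjusted p = 0.257), glutamyl-tRNA reductase (Solyc01g106390.3), the first committed enzyme of tetrapyrrole synthesis, fell 2.83-fold. The heat shock list had 11 of 172 members higher and 27 lower (13 and 34 adjusted over the list alone; camera adjusted p = 0.257). NAC factors had 2 of 50 higher and 6 lower (3 and 7 adjusted over the list alone; camera adjusted p = 0.257). Nitrogen remobilisation had 4 of 35 higher and 3 lower (4 and 3 adjusted over the list alone; camera adjusted p = 0.943), with an ammonium transporter (Solyc10g076480.2) 4.17-fold lower. Wound and jasmonate defence had 0 of 38 higher and 2 lower (0 and 2 adjusted over the list alone; camera adjusted p = 0.811), with a proteinase inhibitor (Solyc11g021060.2) 9.71-fold lower. Autophagy had 1 of 30 higher and 0 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.193). Cell cycle and histone genes had 10 of 201 higher and 16 lower (9 and 14 adjusted over the list alone; camera adjusted p = 0.832), and cell wall loosening had 5 of 97 higher and 12 lower (5 and 13 adjusted over the list alone; camera adjusted p = 0.323). Of the tissue markers, epidermis and cuticle had 4 of 115 higher and 10 lower (4 and 9 adjusted over the list alone; camera adjusted p = 0.463). Glandular trichome markers had 3 of 60 higher and 2 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.618), and vascular markers 1 of 48 higher and 5 lower (1 and 3 adjusted over the list alone; camera adjusted p = 0.283). The trichome list also matched genes described as trichome birefringence-like (Solyc03g046270.4, Solyc12g009150.2 and Solyc02g082950.3 among those called). Its counts are therefore no reading of glandular trichomes. Reference genes, matched on words such as actin, tubulin and polyubiquitin, had 1 of 48 higher and 11 lower (1 and 15 adjusted over the list alone; camera adjusted p = 0.0562). The member higher was an actin cross-linking protein gene (Solyc01g010430.4). The lower members with the smallest adjusted p were ubiquitin genes (Solyc08g083120.3, 1.67-fold, and Solyc08g008590.4, 1.82-fold). For ethylene, nitrogen remobilisation, jasmonate signalling and abscisic acid the list's median, mean and camera direction differed in sign or the median was 0. Without WT replicate 1 the number of called members moved more than 1.5 times in 23 of 29 lists, without WT replicate 2 in 22 and without WT replicate 3 in 12. It did so without CR replicate 1 in 10, without CR replicate 2 in 19 and without CR replicate 3 in 24.

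Several genes were close to absent in 1 group. ROC5 (Solyc06g035940.3), a homeodomain factor, was at 0.138 ± 0.159 CPM in CR (8 counts over the group) against 233 ± 38.9 in WT and 186 ± 44.5 in the libraries labelled OE, a log2 fold change against WT of -10.66 (SE 0.44, adjusted p = 5.76e-06). A yippee-like gene (Solyc03g096140.2) was at 43.4 ± 20.8 CPM in CR and 31.1 ± 10.7 in the libraries labelled OE against 0.0969 ± 0.084 in WT (6 counts), and was called in both lines (adjusted p = 0.000163 and 0.000554). Of the 10 largest changes, 6 in CR against WT, 7 in the libraries labelled OE against WT and 7 in CR against the libraries labelled OE had fewer than 4 counts in 1 of the groups.

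The comparison of the libraries labelled OE with WT asks what a raised level of SlWRKY37 would change, but the SlWRKY37 transcript itself was not raised in them. Several genes of heat shock and defence were among those lower. A gene of heat shock protein 90 (Solyc06g036290.3), a chaperone, was 8.06-fold lower (9.68 ± 5.12 against 77.6 ± 22.2 CPM, adjusted p = 0.0035). Its level in CR was similar (9.43 ± 1.69 CPM). The more abundant Hsp90-2 (Solyc07g065840.2) was at 3060 ± 333 CPM in the libraries labelled OE, 3600 ± 308 in WT and 5150 ± 425 in CR. A mitochondrial small heat shock protein (Solyc08g078700.2) was 5.46-fold lower (adjusted p = 0.00354). A glucan endo-1,3-beta-glucosidase (Solyc01g008620.4), a wall hydrolase of the pathogenesis-related class, was 4.69-fold lower (89.4 ± 18.7 against 419 ± 91.8 CPM, adjusted p = 0.00271). A phenylalanine ammonia-lyase (Solyc00g500095.1) was 7.73-fold lower (adjusted p = 0.00124). PIP1 (286 ± 28.9 CPM) was 3.23-fold lower than in WT (adjusted p = 0.00266). Lipoxygenase D was at 141 ± 22.5 CPM and not called (0.17, adjusted p = 0.527). In all, 1133 genes were called, 343 higher and 790 lower, 540 of them at least 2-fold (146 higher, 394 lower). The authors' deposited table marks 734 genes (225 higher, 509 lower), of which 527 were also called here. The number called was 314 without WT replicate 1, 383 without WT replicate 2, 3456 without WT replicate 3 (1603 higher, 1853 lower), 623 without OE replicate 1, 544 without OE replicate 2 and 500 without OE replicate 3.

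Further called genes in the libraries labelled OE were WRKY55 (Solyc04g072070.3, 15.3 ± 3.84 against 85.7 ± 16.4 CPM), WRKY7 (Solyc04g078550.3, 1.71-fold lower), the ammonium transporter (3.78-fold lower) and Pru ar 1 (5.03-fold lower). Also lower were a dehydrin (Solyc02g084840.3, 2.39-fold lower), an ABSCISIC ACID-INSENSITIVE 5-like gene (Solyc09g009490.4, 2.75-fold lower) and a gibberellin receptor (Solyc09g074270.3, 1.55-fold lower). A cytokinin oxidase (Solyc08g061930.4, 1.54-fold), which breaks cytokinin down, a histone H4 (Solyc06g075960.1, 2.19-fold), a second histone H4 (Solyc06r032490.1, 1.74-fold) and a pectinesterase (Solyc03g123620.4, 82.5 ± 15.3 against 35.6 ± 2.74 CPM) were higher. CRF1 (Solyc06g009810.4), an ethylene-responsive factor gene, was 14.3-fold higher (adjusted p = 0.00891). A gene with FBD and leucine-rich repeat domains (Solyc04g078075.1) had 0 counts in WT and in CR and 6.46 ± 1.67 CPM in the libraries labelled OE, at least 125-fold higher than the floor of 3 counts over the WT group.

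The lists lower in the libraries labelled OE began with the cytosolic ribosomal proteins, with 24 of 287 members lower and 0 higher (104 and 5 adjusted over the list alone; median -0.31, camera adjusted p = 4.52e-15; adjusted p = 0.628 with an estimated correlation). The member with the smallest adjusted p (Solyc10g047150.3, 7.94-fold lower, adjusted p = 0.0145) is described as 50S ribosomal protein L4. The list, matched on text, may therefore not be purely cytosolic. Members called lower numbered 0 without WT replicate 1, WT replicate 2 or OE replicate 3, 84 without WT replicate 3, 1 without CR replicate 3, 2 without OE replicate 1 and 3 without OE replicate 2. Senescence markers had 3 of 18 lower and 0 higher (3 and 0 adjusted over the list alone; median -0.28, camera adjusted p = 0.00241; adjusted p = 0.28 with an estimated correlation). In the heat shock list 21 of 172 members were lower and 1 higher (27 and 4 adjusted over the list alone; median -0.05, camera adjusted p = 0.0229; adjusted p = 0.588 with an estimated correlation). This was lost without OE replicate 2 (adjusted p = 0.0958) or OE replicate 3 (0.0535). Pathogenesis-related genes had 15 of 94 lower and 0 higher (23 and 3 adjusted over the list alone; camera adjusted p = 0.0229; adjusted p = 0.673 with an estimated correlation), with a median of 0 beside a mean of -0.32, and the call was lost without OE replicate 1 (adjusted p = 0.302). WRKY factors had 8 of 62 lower and 2 higher (14 and 2 adjusted over the list alone; median -0.14, camera adjusted p = 0.0231; adjusted p = 0.628 with an estimated correlation). The call of the list was lost without WT replicate 3 (adjusted p = 0.158) or OE replicate 2 (0.0856). Reference genes had 3 of 48 lower and 0 higher (12 and 1 adjusted over the list alone; median -0.19, camera adjusted p = 0.0405; adjusted p = 0.628 with an estimated correlation). That call was lost without WT replicate 1 (adjusted p = 0.139), WT replicate 2 (0.0516), WT replicate 3 (0.0516), CR replicate 3 (0.0522), OE replicate 1 (0.0606) or OE replicate 2 (0.107). It was also lost with a term for the replicate number (0.0683), with fry (0.0739) and without genes missing from part of a group (0.052). Fry also lost the calls of ribosomal proteins (adjusted p = 0.0805), pathogenesis-related genes (0.217) and WRKY factors (0.0805), and kept those of senescence markers (0.00851) and heat shock (0.0228).

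The first list higher in the libraries labelled OE was that of the photosystems, with 5 of 102 members higher and 0 lower (7 and 0 adjusted over the list alone; median 0.35, camera adjusted p = 7.23e-08; adjusted p = 0.628 with an estimated correlation). Chlorophyll synthesis had 1 of 31 higher and 0 lower (1 and 0 adjusted over the list alone; median 0.23, camera adjusted p = 0.000854; adjusted p = 0.628 with an estimated correlation). The photosystem list's median deviation was -0.48, -0.15 and 0.02 in WT and 0.37, 0.27 and -0.05 in the libraries labelled OE, so that OE replicate 3 lay below WT replicate 3. Carbon fixation had 0 of 24 members called (0 adjusted over the list alone; median 0.37, camera adjusted p = 0.00241; adjusted p = 0.673 with an estimated correlation). The list call was lost without WT replicate 1 (adjusted p = 0.0742) or OE replicate 1 (0.0606). Chlorophyll breakdown had 0 of 15 members called (0 adjusted over the list alone; median 0.31, camera adjusted p = 0.0145; adjusted p = 0.673 with an estimated correlation). The call was lost without WT replicate 1 (adjusted p = 0.0742), WT replicate 2 (0.0516) or OE replicate 1 (0.097). Cell cycle and histone genes had 4 of 201 higher and 0 lower (3 and 0 adjusted over the list alone; median 0.16, camera adjusted p = 0.0222; adjusted p = 0.588 with an estimated correlation). It was lost without WT replicate 3 (adjusted p = 0.158) or OE replicate 2 (0.0582). No call of a list higher in the libraries labelled OE held with fry. Its adjusted p was 0.171 for photosystems, 0.0805 for chlorophyll synthesis, 0.33 for carbon fixation, 0.201 for chlorophyll breakdown and 0.0532 for cell cycle and histones. The other 18 lists had camera adjusted p values from 0.13 to 0.992. Median, mean and camera direction were not all of 1 sign for abscisic acid, autophagy, ethylene, jasmonate synthesis and the phenylpropanoid list. Among the 24 lists with a called member, that number moved more than 1.5 times in 24 without WT replicate 1, 21 without WT replicate 2 and 22 without WT replicate 3. It did so in 2 without CR replicate 1, 3 without CR replicate 2, 11 without CR replicate 3, 13 without OE replicate 1 and 16 without OE replicate 2 or without OE replicate 3.

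CR was then set against the libraries labelled OE, with the direction again drawn from a group in which SlWRKY37 was at the WT level. SlWRKY53 was lower in CR (-2.53, adjusted p = 0.000976), as were lipoxygenase D (3.48-fold, adjusted p = 0.00054), WRKY81 (2.51-fold, adjusted p = 0.00133) and notabilis (39.9 ± 5.71 against 117 ± 30.5 CPM, adjusted p = 0.00375). Glutamyl-tRNA reductase was 4-fold lower (46.4 ± 8.99 against 186 ± 23.8 CPM) and chlorophyllase 2 was 2.68-fold lower. A cytokinin riboside 5'-monophosphate phosphoribohydrolase (Solyc06g075090.4), which activates cytokinin, was 3.56-fold higher in CR (121 ± 18.3 against 34.1 ± 4.24 CPM, adjusted p = 0.00243). Genes of the same description were lower in CR than in WT (Solyc04g081290.3, 3.32-fold, adjusted p = 0.00423, and Solyc08g062820.3, 1.6-fold, adjusted p = 0.00505). The zinc finger gene 34 (Solyc04g064770.1) stood at 14 ± 1.9 CPM against 0.257 ± 0.113 in the libraries labelled OE and 0.383 ± 0.185 in WT (adjusted p = 0.000128). In all, 781 genes were called, 240 higher and 541 lower in CR, 479 of them at least 2-fold (115 higher, 364 lower). The authors' deposited table, which runs as OE over CR, marks 848 genes (637 higher, 211 lower). The number called was 1398 without WT replicate 3 (479 higher, 919 lower), 469 without CR replicate 1, 410 without CR replicate 2, 249 without CR replicate 3, 500 without OE replicate 2 and 412 without OE replicate 3.

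Also lower in CR than in the libraries labelled OE were a pair of histone H3 genes (Solyc01g074000.3, 3.29-fold, and Solyc01g086820.4, 3.51-fold), a pair of GRAS factors of the gibberellin list (Solyc12g005340.3, 2.75-fold, and Solyc06g035620.3, 2.17-fold) and a cysteine protease (Solyc02g077050.3, 2.57-fold). So were a chalcone-flavonone isomerase family gene (Solyc05g010320.4, 2.48-fold), NAC14 (Solyc06g073050.2, 2.01-fold) and the proteinase inhibitor (21.9-fold, with 48.1 ± 35.7 CPM in the libraries labelled OE). Higher in CR were a xyloglucan endotransglycosylase (Solyc09g092520.3, 3.14-fold), a pair of PHYTOCHROME KINASE SUBSTRATE 3-like genes (Solyc06g069880.1, 1.75 on the log2 scale, and Solyc03g116160.1, 1.92-fold), ethylene response factor 4 (2.16-fold) and a NAC gene (Solyc07g066330.3, 1.82-fold). A pentatricopeptide repeat gene (Solyc06g010275.1) had 0 counts in CR and 14.5 ± 2.53 CPM in the libraries labelled OE, so it was at least 280-fold lower in CR than in the other group.

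WRKY factors were the list with the smallest p in this comparison, with 13 of 62 members lower in CR and 0 higher (18 and 3 adjusted over the list alone; median -0.27, camera adjusted p = 3.06e-08; adjusted p = 0.29 with an estimated correlation), and 8 were lower without CR replicate 3. Light signalling had 3 of 50 higher and 0 lower (6 and 0 adjusted over the list alone; median 0.12, camera adjusted p = 0.000359; adjusted p = 0.293 with an estimated correlation). Auxin had 4 of 111 higher and 2 lower (4 and 2 adjusted over the list alone; median 0.15, camera adjusted p = 0.00299; adjusted p = 0.293 with an estimated correlation). Cell cycle and histone genes had 7 of 201 lower and 3 higher (29 and 4 adjusted over the list alone; median -0.15, camera adjusted p = 0.00483; adjusted p = 0.293 with an estimated correlation). Cell wall loosening had 9 of 97 lower and 3 higher (20 and 4 adjusted over the list alone; median -0.2, camera adjusted p = 0.00483; adjusted p = 0.551 with an estimated correlation). That call was lost without OE replicate 3 (adjusted p = 0.0908). Vascular markers had 2 of 48 lower and 0 higher (12 and 1 adjusted over the list alone; median -0.3, camera adjusted p = 0.00299; adjusted p = 0.596 with an estimated correlation). Its call too was lost without OE replicate 3 (adjusted p = 0.0552). The phenylpropanoid and flavonoid list had 10 of 79 lower and 4 higher (20 and 8 adjusted over the list alone; median -0.18, camera adjusted p = 0.0172; adjusted p = 0.293 with an estimated correlation). This was lost without CR replicate 3 (adjusted p = 0.0734) or OE replicate 3 (0.0674).

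Gibberellin genes had 3 of 24 lower and 0 higher (4 and 0 adjusted over the list alone; median -0.1, camera adjusted p = 0.0217; adjusted p = 0.293 with an estimated correlation). The call of the list was lost without CR replicate 3 (adjusted p = 0.0734). Senescence markers had 2 of 18 lower and 0 higher (8 and 1 adjusted over the list alone; median -0.35, camera adjusted p = 0.0279; adjusted p = 0.293 with an estimated correlation). The list call was lost without CR replicate 3 (adjusted p = 0.0747). Ribosomal proteins had 0 of 287 lower and 1 higher (0 and 0 adjusted over the list alone; median -0.13, camera adjusted p = 0.0156; adjusted p = 0.827 with an estimated correlation). The call was lost without CR replicate 2 (adjusted p = 0.779), OE replicate 1 (0.22) or OE replicate 2 (0.188). Photosystem genes had 1 of 102 lower and 0 higher (0 and 0 adjusted over the list alone; median -0.12, camera adjusted p = 0.039; adjusted p = 0.792 with an estimated correlation). It was lost without CR replicate 3 (adjusted p = 0.452), OE replicate 1 (0.481) or OE replicate 2 (0.204). Wound and jasmonate defence had 1 of 38 lower and 1 higher (9 and 2 adjusted over the list alone; median -0.51, camera adjusted p = 0.0413; adjusted p = 0.551 with an estimated correlation). This was lost without WT replicate 3 (adjusted p = 0.053), CR replicate 1 (0.0708), CR replicate 2 (0.0912), CR replicate 3 (0.0593) or OE replicate 2 (0.0949). Pathogenesis-related genes had 0 of 94 called (0 adjusted over the list alone; median -0.25, camera adjusted p = 0.0441; adjusted p = 0.642 with an estimated correlation). The call of the list was lost without WT replicate 1 (adjusted p = 0.0571), CR replicate 1 (0.184), CR replicate 2 (0.0912), OE replicate 2 (0.0847) or OE replicate 3 (0.321). With fry the calls of cell wall loosening (adjusted p = 0.156), vascular markers (0.252), ribosomal proteins (0.4) and photosystems (0.4) were lost. So were those of wound and jasmonate defence (0.217) and pathogenesis-related genes (0.265). The other 16 lists had camera adjusted p values from 0.0604 to 0.958. Median, mean and camera direction differed in sign for epidermis, ethylene, jasmonate signalling, heat shock and reference genes. Of the 26 lists with a called member, that number moved more than 1.5 times in 2 without WT replicate 1, 5 without WT replicate 2 and 15 without WT replicate 3. It did so in 16 without CR replicate 1, 19 without CR replicate 2, 23 without CR replicate 3, 8 without OE replicate 1, 13 without OE replicate 2 and 16 without OE replicate 3.

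**Figure D2:**
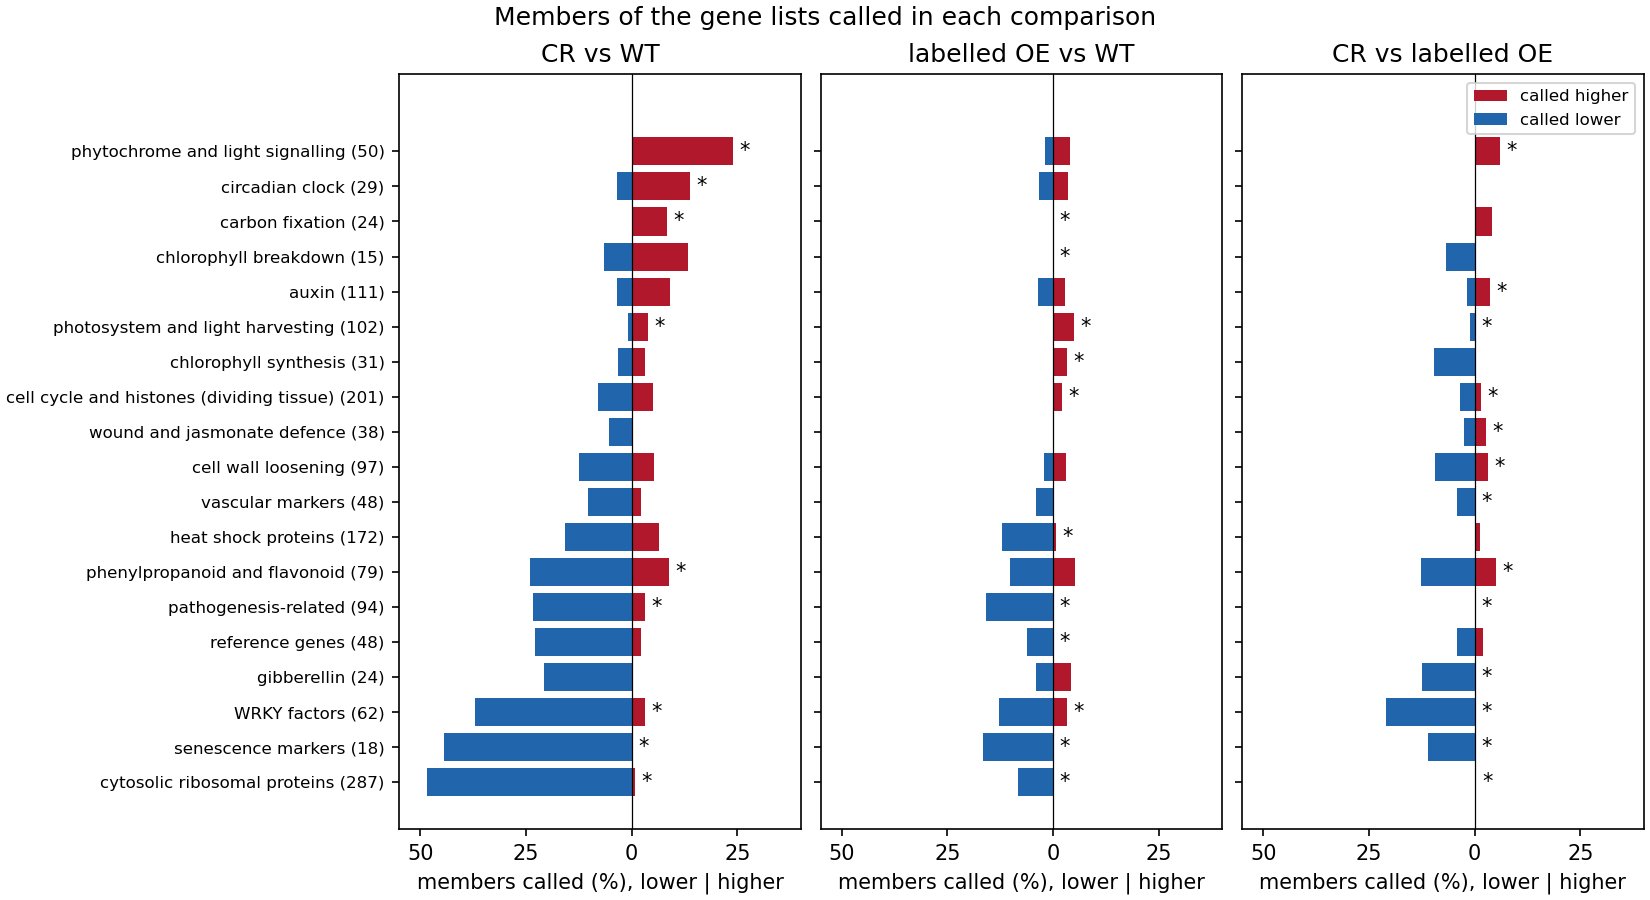
Percent of the tested members of each gene list (number tested in brackets) called higher (red, to the right) or lower (blue, to the left) in each comparison, for lists called in at least 1 comparison; an asterisk marks a camera adjusted p under 0.05 at the preset correlation. No asterisk held with an estimated correlation. Of 62 WRKY factors 23 were called lower and 2 higher in CR against WT (adjusted p = 0.108 with an estimated correlation), and 13 lower and 0 higher against the libraries labelled OE (0.29).

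The mutant and the line labelled OE were also compared jointly with WT, since opposite changes would be sought from loss and gain of a factor. PIP1, Pru ar 1, the ammonium transporter and the mitochondrial small heat shock protein were lower in both lines, and the yippee-like gene was higher in both. Of the genes called in both, 859 changed the same way (201 higher, 658 lower) and 9 changed in opposite ways. Independent lists of these sizes would share 97.3 in the same direction (18.9 higher, 78.4 lower) and 77.7 in opposite directions. The log2 fold changes of both lines had a correlation of 0.566 across genes, which are not independent replicates, against 0.499 (0.452 to 0.542) in 20 simulations of unchanged groups against the shared WT libraries. Their covariance was 0.322 against a simulated mean of 0.0627, a difference of 0.259. With 3 WT libraries the controls could not be divided into groups of at least 2, so part of the excess may come from the shared controls. Both lines together against WT gave 2866 called genes, 909 higher and 1957 lower, with 899 at least 2-fold (154 higher, 745 lower). That number was 1035 without WT replicate 1, 1195 without WT replicate 2, 4796 without WT replicate 3 (2121 higher, 2675 lower) and 1809 without CR replicate 3. Genes changed the same way numbered 235 without WT replicate 1, 292 without WT replicate 2, 2675 without WT replicate 3, 490 without CR replicate 3, 444 without OE replicate 1, 419 without OE replicate 2 and 373 without OE replicate 3.

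Of the 9 genes that changed in opposite directions, 7 were higher in CR and lower in the libraries labelled OE and 2 the reverse. They include a 3-ketoacyl-CoA synthase (Solyc09g065800.4), an enzyme of very-long-chain fatty acid synthesis, at 4.95 ± 1.18 CPM in CR, 1.72 ± 0.289 in WT and 0.679 ± 0.179 in the libraries labelled OE. The chalcone-flavonone isomerase family gene stood at 14.4 ± 0.491, 23.3 ± 3.09 and 35.7 ± 6.1 CPM in the same order. A further 6 were chosen after their values were seen: VQ motif gene 29 (Solyc09g008750.1), a gene described as transporter arsB (Solyc03g025350.3), a transmembrane protein 184C gene (Solyc01g150165.1), Solyc09r042110.1, an S-ribonuclease binding protein gene (Solyc02g069180.4) and a transmembrane protein gene (Solyc04g077500.4), all higher in CR and lower in the libraries labelled OE. Their log2 fold changes in CR ran from 0.34 to 1.3. The number of genes changed in opposite directions was 3 without WT replicate 1, 2 without WT replicate 2, 30 without WT replicate 3, 5 without CR replicate 1, 3 without CR replicate 2, 2 without CR replicate 3, 3 without OE replicate 2 and 5 without OE replicate 3.

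**Figure D3:**
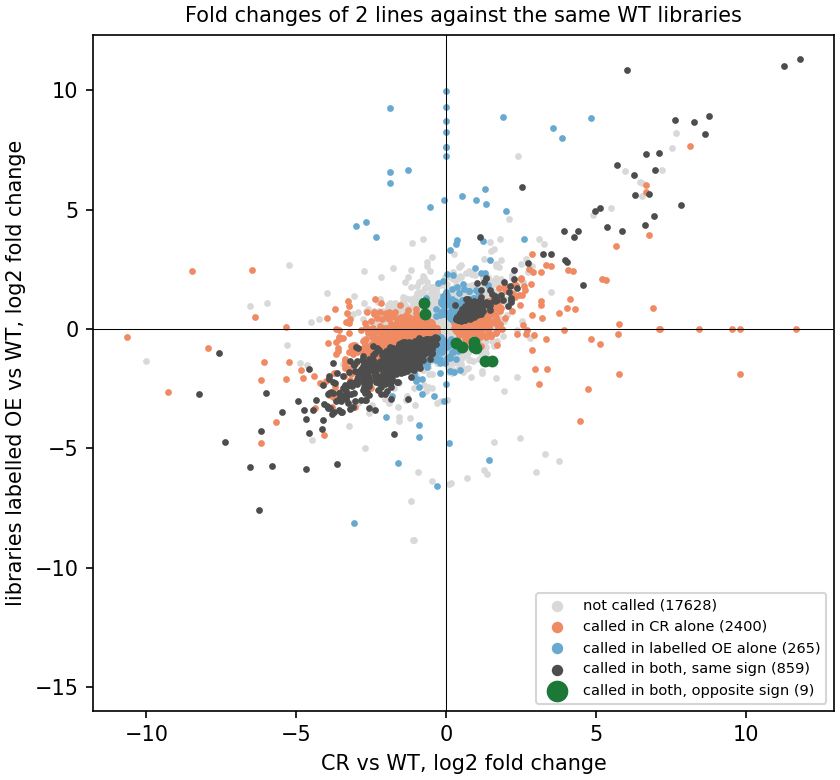
Log2 fold change of each tested gene in CR against WT (horizontal axis) and in the libraries labelled OE against the same WT libraries (vertical axis), with genes coloured by the comparisons that called them. Genes called in both lie mainly along 1 diagonal, 859 with the same sign and 9 with opposite signs, on axes that share the WT libraries.

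Annotation terms were tested on the called genes of each comparison and direction, and 69 were enriched. Genes lower in CR than in WT were enriched for the KEGG ribosome pathway (145 of 344 genes against 44.4 by chance, adjusted p = 1.54e-43), plant-pathogen interaction (65 of 219, adjusted p = 8.99e-10) and protein processing in the endoplasmic reticulum (58 of 224, adjusted p = 2.23e-06). They also held 15 of 38 genes of flavonoid biosynthesis (adjusted p = 0.000976) and 13 of 29 of abscisic acid-activated signalling (adjusted p = 0.00043). The fixed abscisic acid list, by contrast, was not called in CR (camera adjusted p = 0.866) or in the libraries labelled OE (camera adjusted p = 0.845). Genes higher in CR were enriched for starch and sucrose metabolism (22 of 137) and plant hormone signal transduction (31 of 245), each with an adjusted p of 6.98e-05, and for circadian rhythm (6 of 17, adjusted p = 0.0199). In the libraries labelled OE, lower genes were enriched for protein processing in the endoplasmic reticulum (32 of 224, adjusted p = 6.28e-08), plant-pathogen interaction (28 of 219, adjusted p = 5.06e-06), abscisic acid-activated signalling (8 of 29, adjusted p = 0.00101) and cellular response to heat (5 of 12, adjusted p = 0.00317). Higher genes there were enriched for starch and sucrose metabolism (12 of 137, adjusted p = 0.000256). Genes lower in CR than in the libraries labelled OE were enriched for flavonoid biosynthesis (10 of 38, adjusted p = 7.42e-07), and genes higher there for MAPK signalling (9 of 182, adjusted p = 0.0107). Plant-pathogen interaction was enriched in both directions there (16 of 219 lower, adjusted p = 0.00102; 9 higher, adjusted p = 0.0219). For both lines together, genes higher than in WT were enriched for starch and sucrose metabolism (23 of 137, adjusted p = 5.74e-07) and lower ones for the ribosome (139 of 344, adjusted p = 2.43e-42) and abscisic acid-activated signalling (12 of 29, adjusted p = 0.000958). The number of enriched terms was 34 without WT replicate 1, 45 without WT replicate 2, 183 without WT replicate 3 and 40 without CR replicate 3.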

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

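One alternative was chosen after the results were seen, leaving out genes missing from part of a group; all others were planned. Under it the counts of called genes were 3378, 1176, 845 and 2892 for CR vs WT, OE vs WT, CR vs OE and both lines vs WT, each within 1.5 times the reported count. RLE scaling, no filter, the CPM filter and limma-voom also left every count of genes, shared genes and terms within 1.5 times. DESeq2 raised OE vs WT to 2297 (914 higher, 1383 lower), CR vs OE to 1698, genes changed the same way to 1628, the opposite way to 30 and terms to 120. A fit of only OE and WT gave 545 genes, with fewer libraries to estimate the spread. Replicate numbers did not pair the samples: same-numbered libraries had correlated deviations from -0.24 to 0.39, and not every library correlated best with its own number. WT replicate 3, CR replicate 1 and OE replicate 1 deviated alike. OE replicate 1 correlated at 0.39 with CR replicate 1 and at 0.29 with WT replicate 3, and the latter 2 at 0.22. Whether those 3 libraries share a day or batch was not tested, and no label records it. Among the other pairs the highest was WT replicate 1 with CR replicate 3 (0.23). With the replicate block, OE vs WT gave 622 genes, CR vs OE 479, same-way genes 481 and opposite-way genes 4. With an estimated correlation 0, 0 and 0 lists were called, and fry, which asks whether a list's own genes move on balance 1 way, gave 12 lists in CR vs WT, 3 in OE vs WT and 8 in CR vs OE. Lists that fry called and camera at the preset correlation did not were autophagy, gibberellin, heat shock, jasmonate synthesis and reference genes in CR vs WT, and the clock in OE vs WT and in CR vs OE. Camera calls that fry lost were carbon fixation and photosystems in CR vs WT, and all but senescence markers and heat shock in OE vs WT. In CR vs OE it lost cell wall loosening, vascular markers, ribosomal proteins, photosystems, wound and jasmonate defence and pathogenesis-related genes. The cause of these shifts was not tested. Leaving out 1 library gave from 1454 (without CR replicate 3) to 5101 (without WT replicate 3) genes in CR vs WT, from 314 (without WT replicate 1) to 3456 (without WT replicate 3) in OE vs WT, from 249 (without CR replicate 3) to 1398 (without WT replicate 3) in CR vs OE, and from 1035 to 4796 (without WT replicate 1 and 3) for both lines. Same-way genes ran from 235 to 2675 and terms from 34 to 183 (both without WT replicate 1 and 3), and opposite-way genes from 2 (without WT replicate 2 or CR replicate 3) to 30 (without WT replicate 3). Lists called ran from 6 to 12 in CR vs WT, from 7 (without OE replicate 2) to 11 in OE vs WT and from 8 (without CR replicate 3) to 14 in CR vs OE. Of 4302 values for called named genes 3681 kept the call, 621 lost it and 0 changed sign, and of 462 for called lists 362 kept it and 100 lost it. Of 221 values for named genes not called, 8 were newly called and 8 changed sign. LATE ELONGATED HYPOCOTYL in CR vs WT (-0.04 with all libraries) was at 0.03 with limma-voom, 0.28 without WT replicate 3, 0.04 without CR replicate 1 and 0.11 without CR replicate 2 (lowest -0.27 without CR replicate 3). The other changes of sign were SlSGR1 in CR vs OE (0.05 without CR replicate 3 and 0.22 without OE replicate 1, lowest -0.19) and allene oxide synthase (Solyc04g079730.1, OE vs WT) at 0.16 without OE replicate 1 and 0.19 without OE replicate 3 (lowest -0.74 without OE replicate 2), against -0.08 with all libraries. At this depth and number of libraries, simulated changes of 1.5-fold were recovered in 10.8% (CR vs WT), 6.2% (OE vs WT) and 12.3% (CR vs OE) of genes. Those simulations changed 195 or 196 genes, and recovery with as many changed genes as were called here was not simulated.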

Other observations

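Of the tests below, those of WT replicate 3 as the cause of shared changes, of neighbouring genes in CR and the libraries labelled OE, and of both explanations for SlWRKY37 were chosen only after the result was seen; the others were written before. Some called genes of smaller groups were not described above. In CR, DnaJ protein ERDJ3B (Solyc01g079610.3), a co-chaperone of the endoplasmic reticulum, fell by 2.43 on the log2 scale, while the Hsp70 exchange factor FES1 (Solyc09g011030.3) rose 1.54-fold. A GDSL lipase gene (Solyc10g076740.3) had a log2 fold change of 1.93 and a non-specific lipid transfer protein gene (Solyc10g075070.3) one of -1.50. Pectinesterase 1 (Solyc03g112970.1), which removes methyl groups from pectin, fell 3.81-fold in CR, and a histone H2B (Solyc06g075800.1) had a log2 fold change of -0.68. In the libraries labelled OE a cytochrome P450 gene (Solyc11g030730.2) had a log2 fold change of -2.70 and a GDSL gene (Solyc11g031960.2) one of -1.04.

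Other splits of the same libraries were run for each result. With 10 splits of 3 against 3 libraries, a share under 0.05 cannot be reached. The real split gave the most genes (1 of 10 as large, itself) in CR against WT (3268, highest other 0), the libraries labelled OE against WT (1133, highest other 5) and CR against them (781, highest other 0). For lists, 4 of 10 splits gave at least the real 9 in CR against WT (highest other 11), and 1 of 10 in the others (11 against 10, and 13 against 11). Over 100 of 840 splits of all 9 libraries, the real split gave the largest values for both lines against WT (2866 genes, highest other 1475), genes changed the same way (859, highest other 355) and enriched terms (69, highest other 43), with 1 split as large each, the real one. This argues against all 9 libraries being of 1 kind and shows no more. Splits that mix the groups widen the spread within them, and 89 of the 99 other splits called no gene for both lines. No drawn split kept all 3 groups whole with CR or OE as the control. For genes changed in opposite ways (9, highest other 0, 1 split as large) the splits decide nothing, since 93 of the 99 other splits had no gene called the same way in both lines either. The split with 1475 genes kept the 3 WT libraries together. The highest other values for same-way genes and terms came from a split that took the 3 CR libraries as the shared control, so that a distinct group used as control also gave 355 same-way genes.

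The first pattern is the change that both lines share against WT. Chance values shared through the WT libraries do not account for it alone, because the covariance of the fold changes (0.3216) lay above the highest simulated value, 0.0742. The calls also did not need WT replicate 3, which stands apart from the other WT libraries. Without it 2675 genes changed the same way, 838 of them among the 859 found with all libraries. The rise to 2675 decides nothing, since the WT libraries left were the most alike. WT replicates 1 and 2 correlated at 0.984, and WT replicate 3 at 0.954 and 0.958 with them. Without WT replicate 1 or 2 the number was 235 or 292, and how many chance would give with 2 WT libraries was not simulated. For the ribosomal proteins, matched random lists argue against length and abundance as the whole cause: the median of -0.44 in CR compared with -0.05 to 0.04 in those lists, and that of -0.31 in the libraries labelled OE with -0.01 to 0.08. The random lists drew genes singly from the 50 nearest in length and level, and how close the match came was not recorded. Their range leaves out the correlation among ribosomal genes, estimated at 0.425 in CR vs WT. A candidate explanation that remains open is a difference in growth, harvest or transformation history between WT and both lines, which no label records and which cannot be separated here from an effect of SlWRKY37.

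The second pattern is a set of genes read well in some libraries of a group and missing from others, such as a B3 domain gene (Solyc01g150140.1) with 180, 183 and 0 counts in WT and at least 182 in every other library. In WT, 74 genes had under 4 counts in 1 library and at least 50 in another, against at most 3 in simulated libraries, so counting chance is excluded; 26 of them were read well in replicates 1 and 2 and missing from replicate 3. Linked differences between plants could give such genes, and they would lie together. Among the 52 placed WT genes there were 2 neighbouring pairs, compared with a median of 1 in random sets (permutation p = 0.39). The 31 placed genes of this kind in CR had 3 pairs (random median 0, permutation p = 0.011) and the 37 in the libraries labelled OE had 1 (random median 0, permutation p = 0.5). Without genes that share a description with a neighbour the pairs were 2 in WT (random median 0, permutation p = 0.1), 2 in CR (0, p = 0.025) and 1 in the libraries labelled OE (0, p = 0.3). The groups disagree on few pairs, so linked differences and reads shared between near-identical copies both stay open. These genes were chosen after their values were seen.

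The third pattern is SlWRKY37 at the WT level in the libraries labelled OE. With the labels of CR and OE exchanged, the libraries labelled CR would hold the overexpressing line. The highest of them (30.6 CPM) lay below the lowest WT library (33.1 CPM). That argues against an exchange only if overexpression raises the counted transcript. The values cannot decide it for a line that is silenced or whose transcript is not counted. Libraries labelled OE that held plants of the same kind and growth as WT are argued against by genes read in every library of a group and missing from the other. There were 37 between OE and WT and at most 5 in the other splits of these libraries (binomial p = 1.56e-23 for an equal share in each of 10 splits, with genes taken as independent). It may be that the transgene's transcript differs from the annotated gene, that the gene so described is not the one engineered, or that the line was silenced. The line may also not be the one named. None of these was tested here.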
